A study of Homo sapiens with 12 samples.

How the data were processed

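RNA was measured on 12 single-colour expression arrays with biotin label, 8 of U-H01 and 4 of HBL-1. Per the labels' protocols, cells carrying hairpins against RelB and cRel were divided, 1 part of each transduced population received doxycycline to switch the hairpin on, the other did not, and 2 time points were taken, whose lengths are not given in the sources used here. The sample titles name 2 populations of U-H01, B1 and B2, and 1 of HBL-1, C. The labels do not spell out which hairpin each letter stands for, so RELB and REL, the genes of RelB and cRel, were followed in both lines. The design text also names RelA, for which a knock-down was not analysed here. Groups were taken from the titles, giving 4 arrays of U-H01 labelled uninduced and 4 labelled induced and 2 of each for HBL-1. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

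The authors deposited log2 expression values, made with RMA and Partek per the submitters' processing notes, with no versions given in the sources used here. RMA fits background, quantile normalization and a probe-set summary over arrays together, which brings the arrays to like distributions and can hide a shift of all genes in one direction. The deposited log2 values run from 2.07 to 14.3, and array medians lie between 5.79 and 5.88. The value table holds 33297 probe sets. The platform annotation pairs 19460 of them with 1 gene symbol, 1754 with several and 12083 with none, and only those with 1 symbol were tested, for 18417 genes. Entrez identifiers of 19429 matched the reference gene table of assembly GRCh38.p14, which changed 0 symbols. That table served for names and for the order of neighbouring genes alone, since the build behind the array annotation is not given in the sources used here, and no coordinates are printed. In 769 genes with several probe sets, the 1 with the highest mean over the 12 arrays stood for the gene. Values of 23 genes are not reported here. No 2 arrays held identical values, with 0 such pairs. The number of arrays limits the precision, and low log2 levels near background understate a fold.

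All comparisons came from 1 linear model over the 12 arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes without trend or robust options, so that the 4 groups shared 1 estimate of the spread. The model had 7 terms and left 5 residual degrees of freedom. It held the population, the time point within each line and the induction within each line, and B1 and B2 had their own induction terms where they were compared. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with calls at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

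The choices of groups, tests, alternatives, gene lists and the rule for named genes were made before the data were examined, except the comparison of U-H01 arrays labelled induced with HBL-1, 2 other scalings of the gene lists, and the tests of RELB loss, of a response shared by both lines and of other splits for the time points. For each induction and for the uninduced lines the rule names the 10 largest rises and the 10 largest falls past the threshold, changed the same way in every pair, or with no overlap between the arrays of the lines. For the other tests it names the 5 largest each way. It adds the 5 NF-kB subunit genes in every comparison and the 4 members with the smallest p of each gene list described. Y-linked genes and XIST are left out. Of 34 gene lists fixed, 33 had measured members and were tested with camera in limma, with the correlation between genes preset at 0.01, and again with the correlation estimated. They cover NF-kB targets and pathway parts, B-cell, plasma-cell and lymphoma signatures, antigen presentation, interferon, cell cycle, stress and metabolism, and markers of T and NK cells, of myeloid cells and of stroma, endothelium and epithelium.

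The model was tested on simulated data over 19460 probe sets. For the induction term of U-H01 it recovered 61 of 67 genes changed by 1.41-fold and each of those changed by 2-fold or 4-fold, with 18 of 19260 unchanged probe sets called. For that of HBL-1 it recovered 29 of 67 at 1.41-fold, 66 of 67 at 2-fold and 66 of 66 at 4-fold, with 9 of 19260 unchanged ones called. In the list test, a simulated list of 25 genes shifted by 0.4 log2 was called with either correlation. With the preset correlation, 0 of 20 unshifted lists were called. The simulated genes varied independently, so this does not test the preset correlation on genes that vary together.

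Arrays of the same population and time point are the parts of 1 transduced population per the labels' protocols, which is where the pairing comes from. Deviations of paired arrays from their group means correlated at 0.14 and -0.02 for B1, 0.10 and 0.03 for B2 and 0.09 for HBL-1. The highest correlations of these uninduced arrays with arrays labelled induced outside the pair were 0.016 and 0.13 for B1 and 0.064 and 0.17 for B2. They lay above the partner's value at time point 2 and below it at time point 1. With 2 arrays per group the HBL-1 deviations mirror each other, so both pairs share 1 value. Alternatives tried were a term per pair, no time term, each line fitted alone, quantile normalization, centring on the array median, only probe sets above the median level, all probe sets of the table, the mean of a gene's probe sets, trend and robust options, array weights, and leaving out each array in turn. For comparisons within U-H01, the fit was the same whichever HBL-1 array was left out. For the HBL-1 change, it was the same without either array of a pair. That change then rested on the other pair alone, with the spread taken from U-H01. Such fits are not separate evidence. The lists were also tested on ranks.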

Results

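Gene expression was measured in U-H01, a Hodgkin lymphoma cell line, and in HBL-1, a diffuse large B-cell lymphoma line of the activated B-cell-like type, each carrying doxycycline-inducible hairpins. The 12 arrays comprised 4 arrays of U-H01 labelled uninduced and 4 labelled induced, from the populations B1 and B2 at 2 time points, and 2 uninduced and 2 induced arrays of HBL-1, from the population C at 2 time points. The study asked how depletion of single NF-kB subunits alters expression in the 2 kinds of lymphoma. Values are deposited log2 levels, and changes are log2 differences with the standard error of the fit.

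Arrays of the same group correlated at 0.991 to 0.996 over the 19460 probe sets with 1 gene symbol, which also served for the components below. Induced and uninduced arrays of HBL-1 correlated at 0.992 to 0.994. Arrays of U-H01 labelled induced correlated with the uninduced ones at only 0.893 to 0.910, which overlaps the 0.886 to 0.899 between uninduced U-H01 and HBL-1 arrays. With the HBL-1 arrays they correlated at 0.905 to 0.917, a median of 0.909 against 0.901 with the uninduced U-H01 arrays. The first component carried 51.2% of the variance and the second 41.4%, and they placed the arrays in 3 clusters.

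**Figure D1:**
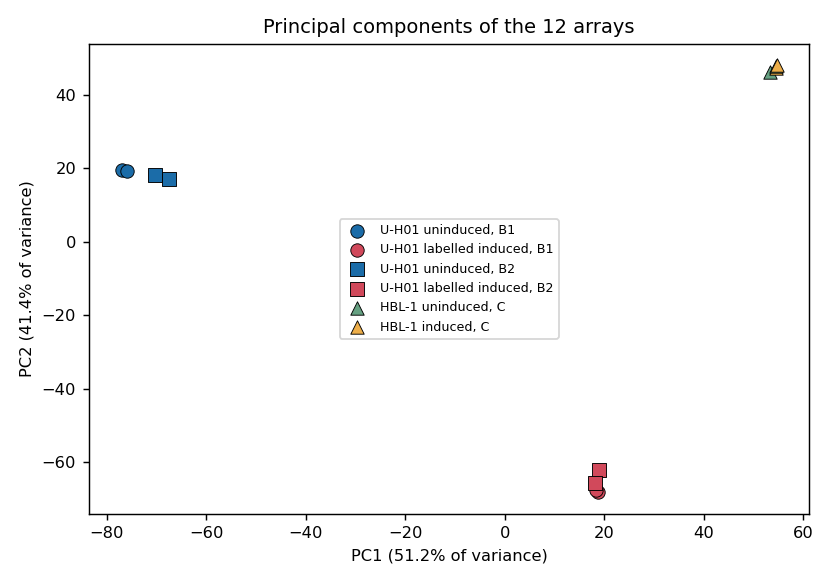
First and second principal components of the 12 arrays, 1 point per array, with colour for the group and shape for the population. The 4 U-H01 arrays labelled induced lie apart from the 4 uninduced ones, while the 4 HBL-1 arrays lie together, with 51.2% and 41.4% of the variance on the axes.

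The labels do not say which hairpin B1 and B2 carry, and RELB and REL are the genes of the 2 subunits named as targets. The change of RELB was negative in all 4 pairs of U-H01 arrays but did not pass the test. Its level was 7.40 ± 0.13 (SD, n = 4) without and 7.25 ± 0.11 (SD, n = 4) in the arrays labelled induced, a change of -0.15 ± 0.09 with an adjusted p of 0.209 from limma and one of 0.201 with the replicate block. Within pairs the differences were -0.0060 and -0.12 in B1 and -0.15 and -0.31 in B2. The 95% interval ran from -0.34 to 0.05, so that a log2 fall larger than the first of these lies outside it. RELB changed by -0.06 ± 0.12 in B1 and by -0.23 ± 0.12 in B2, with adjusted p of 0.743 and 0.172. Because neither RELB, whose interval includes 0, nor REL, whose change was positive, passed as lower, these arrays are called "labelled induced", and directions in U-H01 rest on the labels. In an identity check, described further below, 4 of the 8 U-H01 arrays did not match the others. Rises and falls in U-H01 may therefore be differences between different cells. Among the other subunit genes in U-H01, NFKB2 fell by 0.56 ± 0.09 (adjusted p = 0.000267) and RELA rose by 0.24 ± 0.08 (adjusted p = 0.0229). The RELA call was lost in 5 of 12 fits with 1 array left out, those without U-H01 replicates 1 or 4 labelled induced or uninduced replicates 2, 3 or 4, with adjusted p up to 0.0659. REL at 0.20 ± 0.09 and NFKB1 at 0.16 ± 0.09 did not pass, with adjusted p of 0.0721 and 0.160. REL passed without U-H01 replicate 3 labelled induced (0.26, adjusted p = 0.0401). With all arrays it passed with only probe sets above the median level (adjusted p = 0.0482) and with trend and robust options (0.0432).

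REL, the gene of cRel, was 9.74 ± 0.06 (SD, n = 2) in uninduced and 9.25 ± 0.16 (SD, n = 2) in induced HBL-1 arrays. The change of -0.49 ± 0.12 was negative in both pairs, with a 95% interval of -0.75 to -0.22 and an unadjusted p of 0.00173, and missed the threshold over all genes with an adjusted p of 0.123. The HBL-1 arrays are called induced because this interval excludes 0, but the label is not established past the threshold over all genes, and directions in HBL-1 rest on it too. Adjusted over the list alone, 1 of the 5 subunit genes fell in HBL-1, against 0 over all genes tested. RELA at -0.17, RELB at -0.19, NFKB1 at 0.23 and NFKB2 at -0.17 did not pass in HBL-1, with adjusted p of 0.633 or more. The spread in these tests comes mostly from the U-H01 arrays. A fit of HBL-1 alone leaves only 1 residual degree of freedom, so a call from it rests on little. With HBL-1 fitted alone the same change of REL had an adjusted p of 0.00903, and over all alternatives that p ranged from there to 0.715.

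**Figure D2:**
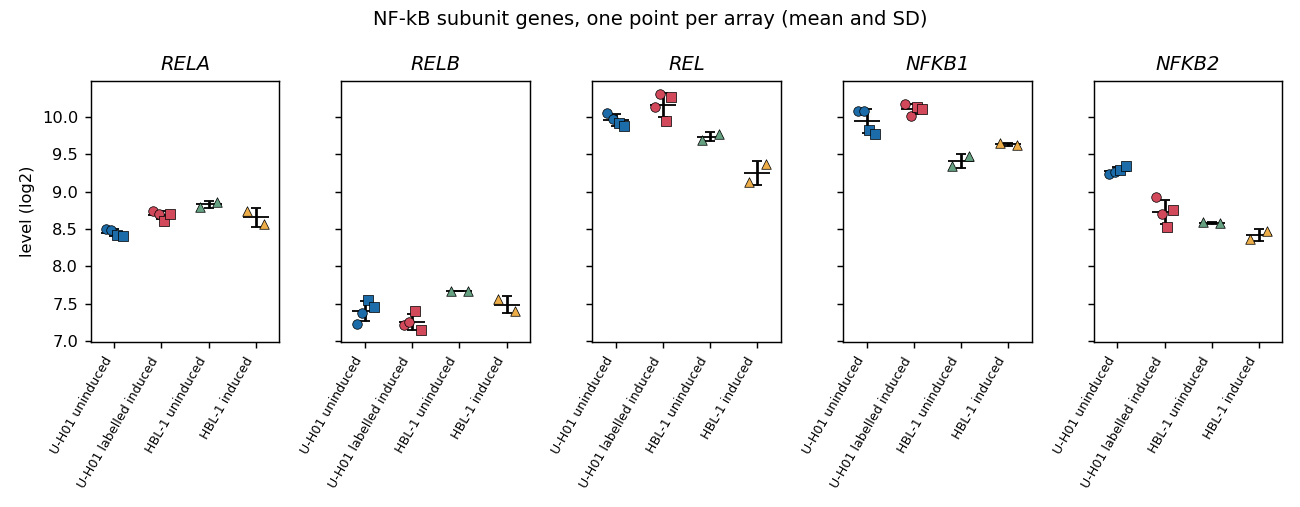
Log2 level of the 5 NF-kB subunit genes, 1 point per array, with the mean and SD of each group (n = 4 for U-H01 groups and n = 2 for HBL-1 groups) and circles, squares and triangles for B1, B2 and C. RELB differs by -0.15 between the U-H01 groups, and REL differs by -0.49 between the HBL-1 groups.

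In U-H01, genes of several kinds differed by a measured 44.2-fold to 144-fold between arrays labelled induced and uninduced ones. The largest measured rise was in SLC38A1, a neutral amino acid transporter, at 6.94 ± 0.14 or 123-fold (n = 4 per group, adjusted p = 1.1e-12). CD38, a surface enzyme of plasma cells and activated lymphocytes, rose 98.3-fold, and SLAMF6, a lymphocyte receptor, rose by 6.45 ± 0.11. ST6GAL1, a sialyltransferase, rose by 6.34 ± 0.10, GLUL, the glutamine synthetase, by 6.20 ± 0.09, and ALDH1A1, a retinaldehyde dehydrogenase, by 6.03 ± 0.14. ENTPD1 rose by 5.91, HLA-DRB5 by 5.71, GPR160 by 5.69 and GPRIN3 by 5.47. The largest measured fall was in GSTM1, a glutathione transferase, by 7.17 ± 0.12 on the log2 scale or 144-fold (adjusted p = 3.3e-13). SULF1, a heparan sulfatase, fell by 7.07, MAOA, a monoamine oxidase, fell by 6.94, and IL13RA1, a cytokine receptor chain, fell by 6.84. GNAQ fell by 6.77, CYP1B1 fell by 6.66, DPP4 fell by 6.59, ALOX15, a lipoxygenase, fell by 6.56, IFI44L fell by 6.50 and SORL1 fell by 6.30. Each of these 20 genes moved the same way in all 4 pairs, which the naming rule required. Their lower group means ran from 3.35 for IL13RA1 to 5.37 for GLUL, against array lower quartiles of 4.18 to 4.28 and medians of 5.79 to 5.88. Levels this low may be background, so these folds can understate the change and their order between genes is not settled, here and in the comparisons between populations and lines.

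Over all genes, 8435 of 18417 passed (45.8%), 4115 higher and 4320 lower in the arrays labelled induced. Of these, 2391 differed over 2-fold and 186 over 16-fold. In 9 genes called here, probe sets of the same gene passed in opposite directions.

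The U-H01 lists below compare labels. In the identity check 4 of the 8 U-H01 arrays did not match the others, which argues against all 8 holding the same cells. These list differences are therefore not read as effects of induction. Interferon-stimulated genes were lower in the arrays labelled induced. Of 34 measured, 26 fell, 1 rose and 7 did not pass, and IFI44L at -6.50, MX1 at -4.65, PARP9 at -4.62 and IFI44 at -4.15 led the list. The list passed camera with an adjusted p of 2.0e-08, and had an adjusted p of 0.261 with an estimated correlation. Of 26 genes known from Hodgkin Reed-Sternberg cells, 15 fell, 5 rose and 6 did not pass. CD274, which encodes a ligand of the receptor PD-1, fell by 5.79, PDCD1LG2, which encodes another, fell by 5.04 and the kinase gene JAK2 fell by 3.27. Against the list, TNFRSF8, the gene of the Hodgkin marker CD30, rose by 4.70, from 6.89 ± 0.21 to 11.6 ± 0.10 (SD, n = 4), and its level in uninduced HBL-1 was 6.63. The adjusted p was 0.00617, and was an adjusted p of 0.389 with an estimated correlation.

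B-cell and plasma-cell genes moved the other way. Of 28 B-cell identity genes, 13 rose, 3 fell and 12 did not pass, with CD79A, a chain of the B-cell receptor, at 5.31, CD22 at 4.11, PAX5, the B-lineage factor, at 2.76 and the kinase gene SYK at 2.53. Of 14 plasma-cell genes, 9 rose and 2 fell, among them PRDM1 at 3.31 and XBP1 at 1.49. Of 9 MHC class II genes, 8 rose, with HLA-DQB1 at 4.11, HLA-DQA1 at 3.71 and HLA-DMA at 1.86, and HLA-DOB fell by 2.64. Of 21 genes of the activated B-cell-like signature, 13 rose and 5 fell, with ENTPD1 at 5.91, IL10 at 3.44 and TNFRSF13B at 2.25, and CYB5R2 fell by 3.74. Adjusted p were 0.00546, 0.00617, 0.00174 and 0.0148 in that order, and each had an adjusted p of 0.389 with an estimated correlation.

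Among NF-kB targets, 14 of 23 receptor and co-stimulatory genes fell and 6 rose (adjusted p = 0.00617), with CD274 and PDCD1LG2 the largest falls described and CD48, at 4.90, and TNFRSF8 as rises. Of 23 cytokine and chemokine genes, 12 fell and 3 rose (adjusted p = 0.0148), and LTA fell by 4.67, TNF fell by 3.31, CCL5 fell by 3.25 and CSF1 fell by 2.31. Both lists had an adjusted p of 0.389 with an estimated correlation, and on ranks the cytokine list had an adjusted p of 0.052. Of 19 immediate-early and AP-1 genes, 9 fell and 1 rose, with DUSP6 at -3.35, ATF3 at -3.25, JUN at -2.91 and DUSP2 at -1.45 (adjusted p = 0.00617, and an adjusted p of 0.261 with an estimated correlation).

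Smaller shifts were seen in 3 further lists. Of 25 oxidative phosphorylation genes 11 rose and 2 fell, with SDHA at 0.95 and NDUFS1 at 0.79. Of 28 ribosomal protein genes 14 rose and 3 fell, with RPL7A at 1.21 and RPL31 at 0.89. Of 24 glycolysis and hypoxia genes 13 rose and 2 fell, with GPI at 1.28 and ENO1 at 0.54, although BNIP3 fell by 3.66 and ALDOC fell by 2.41. Their adjusted p were 0.0307, 0.0322 and 0.0370, and all 3 had an adjusted p of 0.793 with an estimated correlation. With 1 array left out, the glycolysis list lost its call in 6 of 12 fits, with adjusted p up to 0.0968 (without U-H01 uninduced replicate 2). The oxidative phosphorylation list lost it without U-H01 replicate 1 of either group, up to 0.0750, and the ribosomal protein list without replicate 4 of either group, up to 0.0860. After quantile normalization the first 2 had adjusted p of 0.056 and 0.125 with the median still above 0.

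Markers of other cell types did not pass as lists in U-H01. Of 15 T and NK cell markers 4 rose, led by ZAP70 at 2.09, of 14 myeloid markers 1 rose and 2 fell, and of 16 stromal, endothelial and epithelial markers 3 rose and 2 fell, with CDH1 at 2.32 and PECAM1 at -5.60. Their adjusted p were 0.203, 0.622 and 0.810. For these U-H01 lists, counts adjusted over the list alone differed by at most 1 gene in either direction from those over all genes tested. The preset correlation is permissive here: it called 12 of 33 lists for the U-H01 arrays labelled induced but also 11 for the 2 time points and 13 for the difference of that change between them, where 0 genes passed, while the estimated correlation called 0 lists in every comparison.

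**Figure D3:**
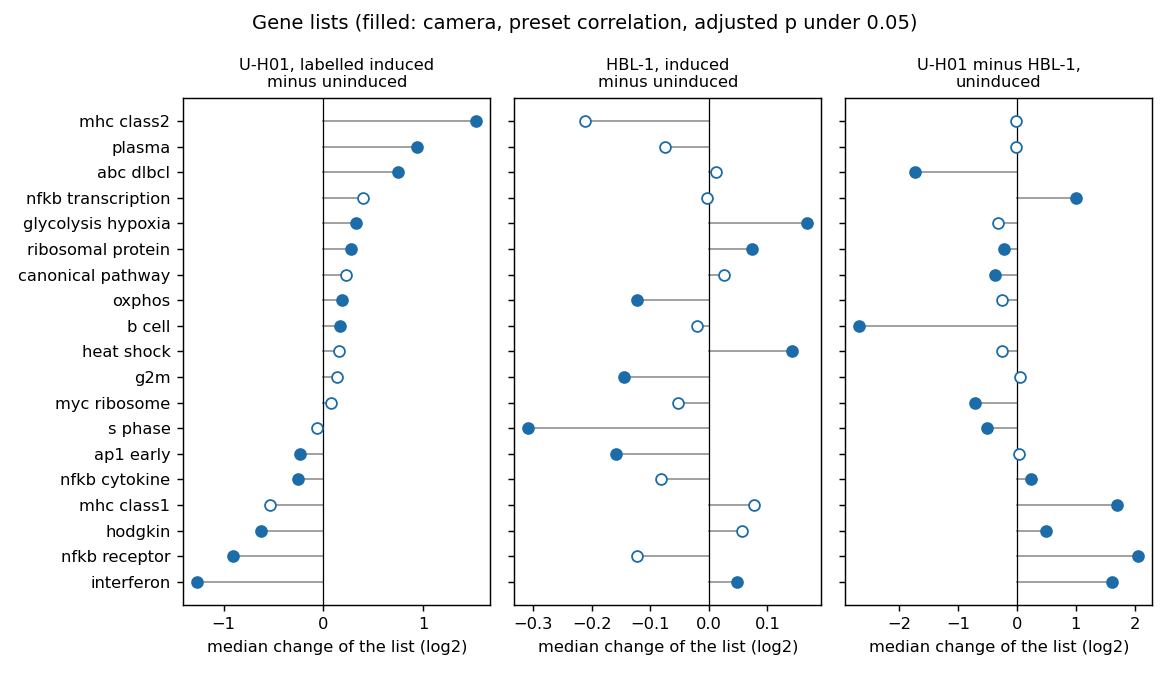
Median log2 change of the gene lists past the threshold in at least 1 of 3 comparisons, 1 point per list, filled where camera with the preset correlation gave an adjusted p under 0.05; the horizontal scales differ between panels. Interferon genes have a median of -1.27 in U-H01 arrays labelled induced and S-phase genes a median of -0.31 in induced HBL-1 arrays, and 0 lists pass with an estimated correlation.

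The 2 U-H01 populations differed from their uninduced arrays in the same genes and by similar amounts, among those named. SLC38A1 rose by 6.95 ± 0.20 in B1 and by 6.94 ± 0.20 in B2, CD38 by 6.64 and 6.60, SLAMF6 by 6.65 and 6.26, and ST6GAL1 by 6.47 and 6.21. ALDH1A1, at 6.30, was among the 5 largest rises in B1 and GLUL, at 6.12, among those in B2. GSTM1 was at -7.44 in B1 and -6.91 in B2, SULF1 at -7.36 and -6.79, MAOA at -7.22 and -6.65, IL13RA1 at -7.05 and -6.63, and GNAQ at -6.96 and -6.59. NFKB2 passed in both, at -0.44 in B1 and -0.68 in B2, and NFKB1 passed in B2 alone, at 0.32 ± 0.11 (adjusted p = 0.0331), with a difference between populations of 0.31 that did not pass (adjusted p = 0.461). The NFKB1 call in B2 was lost with the replicate block (adjusted p = 0.0510), after quantile normalization (0.0676) and without any 1 of the 4 B2 arrays (up to 0.165), and that of NFKB2 in B1 without U-H01 uninduced replicates 1 or 2 or replicate 2 labelled induced (up to 0.176). In B1, 3447 genes rose and 3836 fell, and in B2 3337 rose and 3568 fell. Over all genes the changes of B1 and B2 correlated at 0.957, across genes, which are not independent replicates.

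The change differed between B2 and B1 in 108 genes, 66 with a higher and 42 with a lower value in B2. SPX, a neuropeptide gene, differed by 2.23 ± 0.18, AKR1C2, a steroid-reducing enzyme gene, by 1.92, BMP10 by 1.89, DNM1P46 by 1.61 and CSTA by 1.57. SLFN11 differed by -2.12 ± 0.20, TRIM59 by -1.95, SNORD14E by -1.80, CYRIA by -1.63 and BTN3A3 by -1.47. With 1 array left out, the call of BTN3A3 was lost in 9 of 12 fits (adjusted p up to 0.119), that of CYRIA in 8 (up to 0.115) and that of AKR1C2 in 7 (up to 0.104), each of them without any of the 4 HBL-1 arrays. The other losses were without U-H01 uninduced replicates 1, 3 or 4 or replicates 3 or 4 labelled induced for BTN3A3, uninduced replicates 2, 3 or 4 or replicate 1 labelled induced for CYRIA, and uninduced replicate 1 or replicates 2 or 4 labelled induced for AKR1C2. CSTA lost its call without U-H01 uninduced replicate 1 (adjusted p = 0.0764). The fits without any of the 4 HBL-1 arrays are 1 and the same fit here, since those arrays enter this comparison only through the spread. None of the 5 subunit genes differed between populations past the threshold. With U-H01 fitted alone the count was 36, and with all probe sets of the table tested it was 2.

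The U-H01 changes at both time points correlated at 0.973 across genes. With limma, 0 genes changed between time points and 1422 had an unadjusted p under 0.05. The difference between labelled induced and uninduced arrays was not the same at both time points in 0 genes by limma, with 703 at an unadjusted p under 0.05. Without U-H01 replicate 1 labelled induced the count of 0 was 5.

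Fewer genes differed between induced and uninduced HBL-1 arrays. MPZL2, an adhesion molecule gene, rose by 1.89 ± 0.20 or 3.71-fold (n = 2 per group, adjusted p = 0.00132), MYO1E, a myosin gene, by 1.82 ± 0.13 and CYTH4 by 1.68 ± 0.13. SMARCA1 rose by 1.61, CYTIP by 1.57, the MAP kinase phosphatase gene DUSP5 by 1.38, the scavenger receptor gene CD36 by 1.28, JAML by 1.28, MTARC2 by 1.25 and SQOR by 1.24. IDO1, which encodes a tryptophan-degrading enzyme, fell by 1.99 ± 0.16 on the log2 scale or 3.98-fold (adjusted p = 0.000242), from 9.99 ± 0.02 to 7.99 ± 0.19 (SD, n = 2). PIEZO2, an ion channel gene, fell by 1.72, the early response gene EGR1 fell by 1.58, NLRP11 fell by 1.54, the histone gene H2BC12 fell by 1.45 and ZBTB38 fell by 1.28. PDGFD fell by 1.24, TGFBR3 fell by 1.18, ROCK1P1 fell by 1.14 and SORL1 fell by 1.09. Each of these 20 genes moved the same way in both pairs, which the naming rule required. Of the 20, 13 lost their call with 1 HBL-1 array left out. DUSP5 (adjusted p up to 0.576), PDGFD (0.501), SORL1 (0.283), SQOR (0.205), JAML and PIEZO2 (both 0.198), NLRP11 and TGFBR3 (both 0.180) and MTARC2 (0.0826) lost it without any 1 of the 4 arrays. ZBTB38 (0.283), H2BC12 (0.198) and EGR1 (0.0826) lost it without either replicate 2 array, and ROCK1P1 (0.0955) without either replicate 1 array.

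NFKBIA, the inhibitor gene that NF-kB itself induces, fell by 0.89 ± 0.13 in HBL-1 (adjusted p = 0.0117), the only one of 19 feedback genes to pass. Of 21 activated B-cell-like genes, 2 fell, TNFRSF13B at -0.65 and PIM1 at -0.64, and 0 rose. Adjusted over the list alone, 2 feedback genes and 3 activated B-cell-like genes fell. Neither list passed camera, with adjusted p of 0.325 and 0.392. CD24 rose by 0.95 and JAK2 by 0.74. Whether any of these single genes kept a call with 1 array left out was not examined. In all, 111 of 18417 genes passed, 77 higher and 34 lower, with 35 over 2-fold, and 1794 had an unadjusted p under 0.05. This count depends on the arrays: it was 15 without either HBL-1 replicate 1 array and 8 without either HBL-1 replicate 2 array. It was 868 with HBL-1 fitted alone, which included all 111 but left only 1 residual degree of freedom. It was 214 with array weights, 73 with probe sets above the median level and 38 with all probe sets tested.

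**Figure D4:**
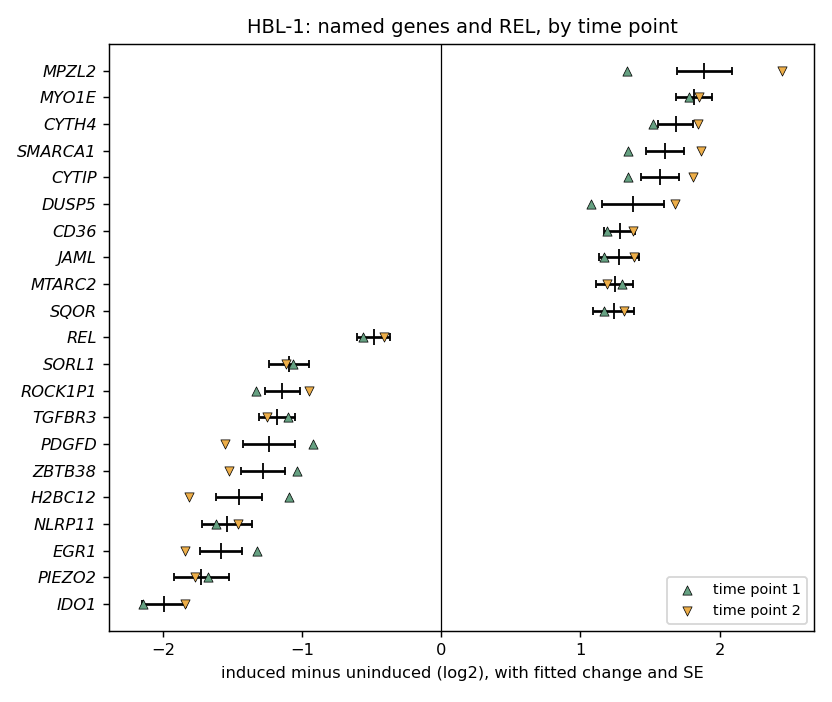
Log2 change on induction of HBL-1 for 20 named genes and REL, with the fitted change and its SE and 1 triangle for each of the 2 time points. IDO1 lies at -1.99, MPZL2 at 1.89 and REL at -0.49. Each gene lies on the same side of 0 at both time points, which the naming rule required of the 20 but not of REL.

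As a list, DNA replication and G1/S genes were lower in induced HBL-1. Their median was -0.31 over 29 genes, of which 0 passed over all genes tested and 3 fell when adjusted over the list alone. GINS2 was at -0.58, PCNA at -0.49, E2F1 at -0.42 and MCM6 at -0.42, and none of these passed over all genes. The list had an adjusted p of 3.1e-10, and an adjusted p of 0.833 with an estimated correlation. Mitosis genes (median -0.14, adjusted p = 0.00961) and oxidative phosphorylation genes (median -0.12, adjusted p = 0.00961) were lower as lists, with 0 members passing. Heat-shock chaperones (median 0.14, adjusted p = 0.00961), glycolysis and hypoxia genes (median 0.17, adjusted p = 0.0208), ribosomal protein genes (median 0.07, adjusted p = 0.0208) and interferon genes (median 0.05, adjusted p = 0.0208) were higher as lists, again with 0 members passing. Adjusted over the list alone, 3 interferon genes rose, and 0 genes of the other 5 lists passed. All 6 had an adjusted p of 0.833 with an estimated correlation. Among 19 immediate-early genes EGR1 fell and DUSP5 rose (adjusted p = 0.0153, and an adjusted p of 0.701 with an estimated correlation). On ranks the interferon list had an adjusted p of 0.142, after quantile normalization the ribosomal list had one of 0.069, and without an HBL-1 replicate 2 array only 2 lists passed. Of the 8 lists, the replication list alone kept its call in all 12 fits with 1 array left out (adjusted p up to 0.00664). Without either replicate 2 array the mitosis (0.952), oxidative phosphorylation (0.472), interferon and glycolysis (both 0.347) and immediate-early (0.151) lists lost theirs, as did the heat-shock list without either replicate 1 array (0.391) and the ribosomal protein list without any 1 of the 4 arrays (up to 0.151). T and NK cell, myeloid and stromal markers had 0 members passing and adjusted p of 0.455, 0.774 and 0.932.

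The difference between arrays labelled induced and uninduced was not the same in the 2 lines in 5969 genes. Line and hairpin population cannot be told apart in this design, and in U-H01 the difference is one between labels, since RELB did not pass as lower and 4 of the 8 U-H01 arrays did not match the others in an identity check. Taken as HBL-1 minus U-H01, S100A10, a calcium-binding protein gene, differed by 7.31 ± 0.15, IL13RA1 by 7.29, MAOA by 7.16, IFI44L by 7.14 and SULF1 by 7.10. SLC38A1 differed by -7.11 ± 0.24, CD38 by -6.57, ST6GAL1 by -6.45, GLUL by -6.26 and SLAMF6 by -6.17. REL differed by -0.69 ± 0.15 (adjusted p = 0.00301) and RELA by -0.41 ± 0.13 (adjusted p = 0.0325), while NFKB2 at 0.39, RELB at -0.04 and NFKB1 at 0.06 did not pass. The RELA difference lost its call in 8 of 12 fits with 1 array left out, with adjusted p up to 0.274, namely without any uninduced array or replicates 1 or 4 labelled induced of U-H01, or either HBL-1 replicate 2 array, and it had one of 0.0571 after centring. NFKB2 passed without U-H01 replicate 1 labelled induced (0.48, adjusted p = 0.0216), and with all arrays after quantile normalization (0.0403) and with array weights (0.0495). Over all genes the changes in the lines correlated at -0.002, across genes. Of the 77 genes that rose in HBL-1, 19 rose in U-H01 where independent lists would share 17.2, and 30 fell where they would share 18.1 (Fisher's exact test, two-sided, p = 0.00267). Of the 34 that fell in HBL-1, 16 fell in U-H01 where 7.98 would be shared (same exact test, p = 0.00344) and 9 rose where 7.60 would be (p = 0.539). The exact test treats genes as independent, and both lists use 1 shared estimate of each gene's spread. All 4 shared counts lay above those for independent lists, so the excess is not read as a relation between the lines.

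Arrays labelled uninduced U-H01 differed from uninduced HBL-1 by as much, and U-H01 stands for that label here, since the identity check does not settle which of the 8 arrays hold that line. IL13RA1 was higher in U-H01 by 6.96 ± 0.12 or 125-fold (n = 4 and 2, adjusted p = 1.7e-12), MAOA by 6.91, SULF1 by 6.90, ALOX15 by 6.79, DPP4 by 6.78, GNAQ by 6.73, CYP1B1 by 6.66, the decoy receptor gene IL1R2 by 6.56, IFI44L by 6.55 and SLC16A4 by 6.34. Lower in U-H01 were the lysosomal membrane gene LAPTM5 at -7.32 ± 0.16, SLC38A1 at -7.19, the leukocyte tetraspanin gene CD53 at -7.12, ST6GAL1 at -7.00, MS4A1, the gene of CD20, at -6.49, RUBCNL at -6.48, IL17RB at -6.28 and IDO1 at -6.18. The small nucleolar RNAs SNORD116-14 and SNORD116-15 were at -6.57 and -6.24. NFKB2 was higher in U-H01 by 0.70 and NFKB1 by 0.53, RELA was lower at -0.38, and RELB at -0.27 and REL at 0.22 did not pass. Without HBL-1 uninduced replicate 2 the RELA difference had an adjusted p of 0.222, and without HBL-1 uninduced replicate 1 that of NFKB1 had one of 0.0663, while RELB passed without U-H01 replicate 4 labelled induced (adjusted p = 0.0394). With all arrays, RELB passed with only probe sets above the median level (adjusted p = 0.0421) and with array weights (0.0373), and REL after quantile normalization (0.0463). In all, 7888 genes differed, 3820 higher and 4068 lower in U-H01.

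Put against HBL-1 in place of the uninduced ones, the U-H01 arrays labelled induced differed in 7063 genes, in a comparison chosen after the data were examined. The 10 genes named as higher in uninduced U-H01 were picked for a low level in HBL-1, and their mean levels of 3.35 to 5.37 in the arrays labelled induced were low as well, so their differences say little. Of genes at a high level in HBL-1, SLC38A1 lay at -0.25 and did not pass (adjusted p = 0.312), while LAPTM5 at -6.44, MS4A1 at -6.46, RUBCNL at -6.68, IL17RB at -6.10 and IDO1 at -5.99 stayed far lower than in HBL-1. The others were closer to HBL-1 than the uninduced arrays were but passed as lower, with ST6GAL1 at -0.66, CD53 at -1.78, SNORD116-15 at -2.59 and SNORD116-14 at -3.04. All 10 genes at a high level in HBL-1 were picked for lying furthest below it in the uninduced arrays. Smaller differences in other arrays follow in part from that choice. Of the subunit genes, RELB was lower at -0.42 (adjusted p = 0.00785), REL higher by 0.43 (adjusted p = 0.00573) and NFKB1 higher by 0.69 (adjusted p = 0.000176), while RELA at -0.14 and NFKB2 at 0.14 did not pass (adjusted p = 0.294 and 0.398). Of the genes called with either set of U-H01 arrays, 1674 were higher than in HBL-1 with both, where independent lists would share 664, and 2385 were lower with both, where they would share 853. Another 483 were higher with the uninduced and lower with the other arrays, where 801 would be shared, and 379 went the opposite way, where 707 would be. Unchanged groups simulated against the same controls, counted at the unadjusted p that the real calls reached, shared in the same order at most 59, 65, 0 and 1 genes in 20 draws. With only 2 uninduced HBL-1 arrays, which cannot be split, part of the excess may come from these shared controls.

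By list, arrays labelled induced lay lower than HBL-1 in B-cell identity genes, with 19 of 28 lower and 5 higher (adjusted p = 3.0e-06). They also lay lower in activated B-cell-like genes (15 lower and 3 higher of 21, adjusted p = 0.000129) and replication genes (19 and 2 of 29, adjusted p = 0.000444). In the list on MYC and ribosome biogenesis they lay lower too (15 and 1 of 22, adjusted p = 0.000277). They lay higher in MHC class I genes (8 higher and 1 lower of 10, adjusted p = 6.8e-05), NF-kB-linked transcription factors (11 and 3 of 14, adjusted p = 0.000162) and MHC class II genes (8 and 0 of 9, adjusted p = 4.7e-06). With an estimated correlation the replication list had an adjusted p of 0.744, the ribosome biogenesis list one of 0.701 and the other 5 one of 0.356. All but the MHC class II list passed the same way with the uninduced arrays.

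Among lists in the arrays labelled uninduced, with the same limit on what U-H01 stands for, 22 of 28 B-cell identity genes were lower in U-H01 and 0 higher, with MS4A1 at -6.49, BANK1 at -5.34, SYK at -5.25 and BLNK at -4.14 (adjusted p = 1.6e-14). Of 21 activated B-cell-like genes 18 were lower and 2 higher, with ENTPD1 at -5.80 and PIM1 at -4.40 (adjusted p = 2.2e-08). Of 34 interferon genes 23 were higher and 4 lower, with IFI44L at 6.55, IFI44 at 4.22 and RIGI at 3.60, and with MX2 at -4.90 against the list (adjusted p = 1.6e-09). These 3 lists had an adjusted p of 0.104 with an estimated correlation. Of 10 MHC class I genes 8 were higher, with TAP1 at 3.63 and ERAP2 at 3.49 (adjusted p = 4.3e-05, and an adjusted p of 0.190 with an estimated correlation). Of 26 Hodgkin genes 14 were higher and 5 lower, with GATA3 at 5.14, PDCD1LG2 at 4.94, CCL5 at 3.56 and JAK2 at 3.52 (adjusted p = 0.000202, and an adjusted p of 0.162 with an estimated correlation).

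NF-kB receptor genes were higher in 15 and lower in 6 of 23, with CD86 at 5.37 and TNFRSF9 at 4.64, NF-kB cytokine genes higher in 11 and lower in 3 of 23, with LTA at 6.27 and CXCL10 at 5.94, and NF-kB-linked transcription factors higher in 11 and lower in 2 of 14, with MYB at 3.46 and BATF3 at 3.46. Their adjusted p were 0.000535, 0.000897 and 0.000535, and all 3 had an adjusted p of 0.224 with an estimated correlation. Components of B-cell receptor and canonical NF-kB signalling were lower in 9 and higher in 3 of 16, with CD79A at -5.53 and PRKCB at -4.73 (adjusted p = 0.00906, an adjusted p of 0.162 with an estimated correlation, and one of 0.143 on ranks). Genes of a list on MYC and ribosome biogenesis were lower in 15 and higher in 1 of 22, with PES1 at -1.53 (adjusted p = 0.000535). Replication genes were lower in 19 and higher in 3 of 29, with TK1 at -1.83 and MCM5 at -1.76 (adjusted p = 0.000954). Ribosomal protein genes were lower in 13 and higher in 0 of 28, with RPL7A at -0.92 (adjusted p = 0.0212). With an estimated correlation these 3 had adjusted p of 0.757, 0.802 and 0.860, and the ribosomal protein list had one of 0.069 after quantile normalization and lost its call without U-H01 uninduced replicate 4 (adjusted p = 0.0749) or HBL-1 uninduced replicate 2. Markers of T and NK cells, with 2 lower and LCK at -0.78, of myeloid cells, with 1 higher and 2 lower, and of stroma, with 3 higher and 1 lower, had adjusted p of 0.528, 0.653 and 0.694. Counts adjusted over the list alone differed by at most 2 genes in either direction from those over all genes tested.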

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

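The tests of RELB loss, of a response shared by both lines and of other splits for the time points were chosen only after the results they measure had been seen, as was the comparison of U-H01 arrays labelled induced with HBL-1.

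The size of the U-H01 difference stands out: in 5969 genes the difference between arrays labelled induced and uninduced was not the same in HBL-1 and U-H01, by the test of that difference. S100A10 differed by 7.31, IL13RA1 by 7.29, MAOA by 7.16, IFI44L by 7.14, SULF1 by 7.10, SLC38A1 by -7.11, CD38 by -6.57, ST6GAL1 by -6.45, GLUL by -6.26 and SLAMF6 by -6.17, and of the subunit genes RELA differed by -0.41 and REL by -0.69, the RELA call being lost in 8 of 12 fits with 1 array left out. The real split of the 8 U-H01 arrays gave 8435 genes and the highest of the other 34 splits gave 0. Thus 1 of 35 splits was as large. Every other split mixes both groups and puts their large differences into the spread. A count near 0 there was therefore fixed beforehand, so the splits do not exclude chance for the genes. The real split gave 12 lists and the highest other split 10, with 1 of 35 as large. The same list test called 13 and 11 lists for the time by induction and time comparisons, where 0 genes passed. The number of lists is therefore not read as beyond chance. Among the 8 splits that part all pairs, too few for a share under 0.05, the highest other gave 0 genes and 9 lists. For the time points the real split gave 0 genes, so all 35 splits gave at least as many by construction and decide nothing; the split along the induction labels gave 8301.

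Loss of at least 2-fold of RELB mRNA would put that gene at -1 or below, and its interval ended at -0.34. That argues against such a loss only if both parts hold the same cells. If they do not, a RELB difference between the cells could hide a loss, so this test cannot decide. A smaller loss, or a loss of protein, was not tested. A response to doxycycline shared by both lines would move the same genes in HBL-1. Over the 2391 genes changed over 2-fold in U-H01 the slope was 0.0028. That argues against a shared response as the source of the size of these differences. If the parts hold different cells, their differences could hide a smaller shared response, on which this slope cannot decide. Cells of another origin in 1 part of the U-H01 arrays stay open as a candidate explanation. Both tests of it, with predictions fixed beforehand, came out as predicted. A gene's change correlated at 0.177 with that of genes 11 to 30 places away on its chromosome, against at most 0.020 in 100 shuffled orders and 0.220 between uninduced U-H01 and HBL-1, and in an identity check 4 of the 8 U-H01 arrays did not match the others. That check set arrays apart at a gap over 1 log2 in the mean of a fixed set of genes, and replaced, before any result was seen, a planned version that could not run because a gene of it was not measured on its own. The neighbour signal is not specific, because the HBL-1 induction gave 0.088 against at most 0.024 in shuffled orders. GSTM1 and HLA-DRB5, which some human genomes lack, were among the largest differences. GSTM1 lay at 12.4 in uninduced and 5.27 in labelled induced arrays, and HLA-DRB5 at 4.86 and 10.6. Each was thus high in 1 part only, and not in the same part. Which arrays could hold cells other than U-H01, or whether depletion of RelB protein contributes, cannot be decided from these values.

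The change differed between populations B2 and B1 in 108 genes by the test of that difference. SPX differed by 2.23, AKR1C2 by 1.92, BMP10 by 1.89, DNM1P46 by 1.61, CSTA by 1.57, SLFN11 by -2.12, TRIM59 by -1.95, SNORD14E by -1.80, CYRIA by -1.63 and BTN3A3 by -1.47, of which AKR1C2, CYRIA, BTN3A3 and CSTA lost their calls in some fits with 1 array left out. In 79.6% of the genes, 86 of 108, the populations differed more between the uninduced arrays than between those labelled induced, so a difference already present between the uninduced arrays is a candidate explanation for most of them. SPX is such a gene, at -2.35 between uninduced and -0.12 between the other arrays, and TRIM59 is not, at 0.01 and -1.93. In arrays labelled induced, SPX lay at a mean of 3.37 and BMP10 at 3.85, levels that may be background. Background can hide a difference there, so for such genes the count may be set in part by low levels. No biological explanation was tested for the hairpins, whose sequences are not used here.

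Among arrays of U-H01 labelled induced, 1 array median lay apart from the other 3, with a gap of 0.846 of the group's range. Chance flags about 1 in 20 groups, and 74 group tests gave 1 such gap where 3.7 would arise by chance. Probe sets without a single gene name, which the comparisons leave out, also changed: 4344 of 13837 in U-H01 and 17 in HBL-1.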

How the results depend on the processing

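The alternatives with U-H01 arrays labelled induced against HBL-1 and the 2 other scalings of the gene lists were chosen only after the data were examined. Fits without a time term were not run for the time results, nor each line alone for comparisons between lines. The U-H01 count of 8435 lay between 6291 and 8454 over the alternatives, and RELB in U-H01 passed under none. The replicate block gave 8181 genes in U-H01, 87 in HBL-1 and 92 for B2 minus B1. It ended the call of NFKB1 in B2 (adjusted p = 0.0510) and added a stress-response list in U-H01 (0.0458) and a JAK-STAT list in HBL-1 (0.0494), and among named genes and lists pairing changed no other call. No scaling moved the median of all genes by over 0.1 log2. HBL-1 fitted alone leaves only 1 residual degree of freedom, which limits what its calls can show. The HBL-1 count of 111 was 868 with each line fitted alone, 214 with array weights, 73 with probe sets above the median level, 38 with all probe sets tested, and 8 to 149 with 1 array left out. REL in HBL-1, at -0.49 with each line alone, passed there with an adjusted p of 0.00903, within a range up to 0.715. The B2 minus B1 count of 108 was 36 with each line alone, 2 with all probe sets and 212 with trend and robust options, and 15 to 129 with 1 array left out; it was 15 without U-H01 uninduced replicate 1, 20 without any of the other 3 uninduced, 67 without replicate 2 labelled induced, 55 without replicate 4 labelled induced and 36 without any HBL-1 array. The time by induction count was 0 to 5. List counts were 0 with an estimated correlation in all 3 comparisons, 6 in U-H01 and 5 in HBL-1 with probe sets above the median level, 2 to 10 in HBL-1 with 1 array left out, and 7 for the lines with arrays labelled induced. The cause was not tested, except that fewer arrays or more tests leave less power by construction.

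Subunit genes that did not pass changed sign in some fits, and the cause was not tested. With quantile normalization RELB for HBL-1 minus U-H01 was 0.027, NFKB1 in B1 -0.056, and for B2 minus B1 RELA was -0.0083 and REL -0.0078. With centring NFKB1 in B1 was -0.0013, and for time RELA was -0.023 and NFKB2 -0.0062. With 1 array left out, ranges were -0.12 to 0.044 for RELB and -0.013 to 0.14 for NFKB1 in HBL-1 minus U-H01, -0.19 to 0.065 for RELB and -0.060 to 0.069 for NFKB1 in B1, and -0.037 to 0.072 for RELA and -0.15 to 0.15 for REL in B2 minus B1. For time by induction they were -0.016 to 0.083 for RELA, -0.29 to 0.015 for RELB, -0.21 to 0.082 for NFKB1 and -0.27 to 0.19 for NFKB2. For time they were -0.016 to 0.021 for RELA, -0.11 to 0.038 for RELB and -0.059 to 0.11 for NFKB2. Of values of named genes under alternatives, 46 in HBL-1, 37 in B2 minus B1, 9 in HBL-1 minus U-H01, 6 in B2, 5 in U-H01, 3 in B1 and 2 between the uninduced lines no longer passed, the last 5 all of RELA, NFKB1 or NFKB2, and 3 in U-H01, 3 in HBL-1 minus U-H01 and 4 between the lines newly passed. Arrays give no count of molecules, and levels near background limit the size of falls.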

Other observations

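The neighbours of CD274 were tested before their values were seen, but the 3 genes themselves were chosen after their values had been seen.

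Single genes in lists that did not pass as a whole also differed widely in U-H01 arrays labelled induced. CYP51A1, an enzyme gene of cholesterol synthesis, fell by 5.73 ± 0.18 (n = 4 per group) while STARD4 of the same list rose by 2.45. The small heat-shock gene HSPB1 fell by 4.60 ± 0.09, and PSAT1, of serine synthesis, fell by 4.73. Among survival genes linked to NF-kB, BCL2L1 fell by 3.26 and CFLAR fell by 2.54, while MCL1 rose by 1.37. Among feedback genes NFKBIZ rose by 3.73 and TRAF1 by 2.70, while CYLD fell by 2.13, and TNFRSF11A, the gene of the receptor RANK, fell by 5.13. The cytokine receptor genes IL10RA and IL4R lay at -4.72 and -3.22. In HBL-1, DDIT4 at 1.66 ± 0.50 and TNFRSF17 at -1.06 ± 0.33 did not pass (adjusted p = 0.218 and 0.231).

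CD274, PDCD1LG2 and JAK2, which lie near each other on their chromosome, were lower together in U-H01 arrays labelled induced, at -5.79, -5.04 and -3.27. A copy-number difference of that segment between the cells on the arrays is a candidate explanation, offered as a hypothesis. The 20 measured genes next to them, 10 on each side, had a median of -0.61, at percentile 0.603 of such medians over 17744 windows of the genome, and 12 of the 20 fell, 0 rose and 8 did not pass. In the HBL-1 induction the same median lay at percentile 88.5. For uninduced U-H01 minus HBL-1 it was 0.43, at percentile 97.5, with 11 of the 20 higher and 0 lower. For arrays labelled induced minus HBL-1 it was -0.06, at percentile 32.8, with 4 higher and 3 lower. Against HBL-1 the neighbours thus stood apart in the uninduced arrays, as higher. Genes between the 3 did not all follow: PLGRKT fell by 1.76 and INSL6 rose by 1.02, and no DNA was measured here.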
